A study of Drosophila melanogaster with 4 samples.

How the data were processed

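Total RNA of Kc167 cells was labelled with biotin and hybridized to Affymetrix DrosGenome1 arrays, 1 array for each of 4 conditions. The deposited values are signal intensities that the authors computed with MAS5, whose version is not given in the sources used here. Per the file headers, all 4 arrays came from 1 chip lot and were scanned on 1 day after washing on station 2. The irradiated and combined arrays were washed in modules 1 and 2 and scanned first and second, and the control and ecdysone arrays in modules 3 and 4. The number of arrays limits the precision.

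Of 14010 probe sets, 44 are controls and 13966 were analysed. Platform annotation gave 12443 of these 1 gene symbol, 327 several symbols and 1196 none. Gene names were updated through gene identifiers with the Release 6 plus ISO1 MT annotation for 12394 probe sets and kept from the platform annotation for 49, giving 10844 genes. The genome assembly served only as the source of names.

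The deposited signals of each array had a trimmed mean of 200.0 over all probe sets, leaving out 2% at each end. Each array was then scaled to a common trimmed mean of the non-control probe sets, which changed no array by more than 0.0667%. Signals were raised to a floor at the median of all scaled signals, 119.4 units, before log2 differences were taken. Alternative floors lay at the 25th percentile (41.7) and the 60th (173), with no floor as a further alternative. The ecdysone effect was measured in the unirradiated pair (ecdysone against control) and in the irradiated pair (combined against irradiated), and the irradiation effect in the pairs without and with ecdysone. The size rule, which is no test, called a probe set that differed at least 2-fold in the same direction in both pairs. Its noise was gauged with a crossed grouping, control and combined against the single treatments.

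An additive model of both treatments was fitted to the unfloored scaled log2 signals with limma 3.58.1 in R 4.3.3, using an empirical Bayes prior that follows intensity. It covered the 5981 probe sets whose mean log2 signal exceeded the floor, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 1 residual degree of freedom, the departure from additivity. The verbs rose, fell and changed are used for probe sets past this threshold. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

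The genes to be named were fixed by a rule: the 12 with the largest mean difference in each direction among those called by the size rule, for each treatment, and the 5 with the largest interaction in each direction. Other genes were chosen after their values were seen, apart from members of the 27 gene lists. These lists, the comparisons and most alternatives were fixed before the data were examined. They cover ecdysone response, heat shock, cell death, autophagy, radiation response, DNA repair and replication, mitosis, immunity, hemocyte types, JNK, detoxification, P450 enzymes, adhesion, cytoskeleton, glycolysis, growth, lysosome, reference genes, ribosomal proteins and markers of neurons, muscle, fat body, germline and epidermis. Each gene was represented by its probe set with the highest mean signal. Members without a probe set of their own were left out, among them Eip74EF and Eip75B (ecdysone response) and Hsp22 and Hsp23 (heat shock). A list's median difference was placed among 10000 random lists matched on mean signal in 20 bins.

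Alternatives were median scaling, quantile normalization, the values as deposited, other floors, fold thresholds of 1.5 and 3, each pair alone, the mean over all probe sets of a gene, and limma without the trend or with a robust prior. A floor of 500 units, alone and without the trend, was chosen after seeing the data. In limma a floor only selected the probe sets tested, those with a mean above it, and the adjustment ran over these alone.

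The calls were tested on simulated data with 200 of 5981 probe sets changed in 20 runs. Noise was drawn independently for each array from probe sets of similar intensity, as the intensity trend assumes. The rates below therefore do not cover noise particular to a gene or shared between arrays. The size rule called 4.92% of unchanged probe sets and limma 0.139%. Of probe sets changed 4-fold the size rule called 54.4% and limma 24.6%, and of those changed 16-fold 90.1% and 73.8%. Of 100 simulated lists of 20 genes, 2% lay outside the middle 95% of random lists without a shift, and 89% with a log2 shift of 0.5. Present and absent calls and raw image data were not used here.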

Results

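Kc167 cells, a Drosophila melanogaster line derived from embryos and grown in serum-free medium, were profiled with 4 Affymetrix arrays. Cells were incubated for 72 h without hormone or with 10 µM muristerone A, a plant ecdysteroid that acts as an agonist of the ecdysone receptor and is called ecdysone here. They were then mock-treated or exposed to 280 Gy of gamma rays and rested for 90 min before RNA was taken. The 4 conditions were control, ecdysone, irradiated and the combined treatment, with 1 array each, so no value has a replicate and the number of arrays limits the precision. The series title names ecdysone-induced and stress-induced expression, and the crossed design gives each treatment a pair of comparisons that share no array. Each array held 13966 probe sets besides 44 controls, with median signals of 121.4 in control, 124.95 in ecdysone, 118.7 in irradiated and 113.7 in combined. Between 48.8% (combined) and 51.0% (ecdysone) of the probe sets lay above the floor of 119.4 signal units. Values of a gene are log2 differences on floored signals, first in the pair without the other treatment and then in the pair with it. A fold is the mean over both pairs, and "at least" marks a fold whose lower level was at the floor.

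Ecdysone was followed by very large increases in a small set of transcripts. Obp99c, which encodes an odorant-binding protein, rose from 120.5 to 10246 signal units without irradiation and from 55.3 to 17755 with it, at least 113-fold (limma adjusted p = 1.44e-14). Npc2g, of the family of NPC2 sterol-binding proteins, rose at least 26.6-fold. Mtk, which encodes the antimicrobial peptide metchnikowin, rose at least 23.2-fold. The metallothionein gene MtnA rose at least 15.5-fold and Col4a1, a collagen IV chain, also rose at least 15.5-fold. In the other direction Inos, which encodes inositol-3-phosphate synthase, fell by 2.16 and by 1.75 on the log2 scale (limma adjusted p = 3.68e-06).

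Among the 5981 probe sets tested, 119 changed with ecdysone, 86 higher and 33 lower. Of the 12 genes with the largest increases under the size rule, all 12 passed limma. Besides those above they were CG4250 (5.40 and 5.23), CG14629 (4.73 and 4.19), CG42369 (4.22 and 4.06), CG5399 (4.70 and 3.21), nemy (3.70 and 4.15), hll (3.69 and 4.06) and CG5080 (3.47 and 4.20). The other probe set of nemy did not pass and had a mean difference of -0.29. Of the 12 genes with the largest decreases, 7 passed. Ids, which encodes the lysosomal enzyme iduronate 2-sulfatase, fell by 3.45 and by 1.77, and the transporter gene Orct2 fell by 2.41 and by 2.69. CG15211, dj-1beta, AOX1, AdamTS-B and the fatty acid binding protein gene fabp also fell, with fabp at -2.01 and -2.19. The other 5 did not pass limma: salr was at -2.27 and -2.50, CG10062 at -2.07 and -2.53, Ant2 at -2.15 and -2.05, CG31064 at -2.57 and -1.63, and msd5 at -1.93 and -2.21.

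The list of known ecdysone response genes had 22 members above the floor, of which 14 could be tested. The nuclear receptor genes Eip78C (3.95 and 2.99) and Hr4 (2.84 and 2.44, with a mean of 0.52 at its other, weaker probe set) rose, as did Cth, written as Eip55E in the list, at 1.58 and 1.76. None of the tested members fell over all genes, and 4 were higher when adjusted over the list alone, the addition being Eip93F, at least 4.23-fold higher. Hr3, another nuclear receptor gene, was at 1.85 and 1.04 but was too weak for the test. The list median was 0.37, at percentile 99.55 of random lists matched on signal. It was 0.61 in the unirradiated pair and 0.06 in the irradiated pair.

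The immune list holds antimicrobial peptide genes and immune signalling genes. Of its 14 tested members 4 rose, the same number as when adjusted over the list alone, and none fell. These were Mtk (5.82 and 3.25), CecB (3.54 and 1.75), DptB (2.89 and 1.69) and AttD (1.90 and 0.56), all antimicrobial peptide genes. DptB, a diptericin gene, reached 26438 signal units with ecdysone against 3563 in control. The list median was 0.66, at percentile 100 of the random lists.

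Of 9 tested glycolysis genes 4 rose over all genes and 4 when adjusted over the list alone: Ald1 (1.62 and 2.04), Gapdh1 (1.88 and 0.92), Pgk (1.52 and 1.33) and Pglym78 (0.72 and 2.88). The list median was 0.70 at percentile 99.95. The separate control probe set at the 3′ end of the GAPDH transcript went from 963.2 to 8970 signal units without irradiation and from 1853.3 to 10968 with it. The 3′ against 5′ log2 difference of this transcript was 0.30 above control in ecdysone and 1.29 above it in the combined array. In the lysosome list 3 of 12 tested members rose, CtsL1 (written as Cp1, a cathepsin; 1.74 and 1.93), Npc2a (1.68 and 2.25) and Sap-r, the saposin precursor (1.65 and 1.21, with a mean of 0.61 at its other probe set, which did not pass). When adjusted over the list alone 6 were higher, with CtsB, Vha16-1 and spin added, and the list median of 0.38 lay at percentile 98.57, with 92.95 in the unirradiated and 99.02 in the irradiated pair. Of 18 tested genes of oxidative stress and detoxification 3 rose, Cat, which encodes catalase (2.78 and 2.57), MtnA (4.96 and 2.95) and GstE3 (2.80 and 0.98), and 3 when adjusted over the list alone. Their list median lay at percentile 99.24, and at 97.27 in the unirradiated and 88.31 in the irradiated pair alone. Cyp6a8 of the cytochrome P450 list rose by 3.53 and by 2.49. With Npc2a it made 2 of 9 tested members, against 3 when adjusted over the list alone.

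Hemocyte genes moved in both directions. Of 15 tested members Pxn, which encodes peroxidasin (2.37 and 2.97), and Col4a1 (3.92 and 3.99) rose, while the hemolectin gene Hml (-1.70 and -2.21) and Nplp2 (-1.01 and -1.55) fell. Adjusted over the list alone 4 were higher and 3 lower, and the list median of -0.05 lay at percentile 36.04. In the adhesion and matrix list Col4a1 and the neurotactin gene Nrt (3.68 and 1.59, with its other probe set at the floor on all 4 arrays) rose among 14 tested, against 4 higher and 1 lower when adjusted over the list alone. The tubulin gene betaTub97EF (2.06 and 1.75) was the member of the cytoskeleton list that rose among 17 tested, and the same count held when adjusted over the list alone.

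Genes of DNA replication lay low. PCNA, the sliding clamp of DNA polymerase, fell from 3727 to 1771 signal units without irradiation and from 4397 to 1809 with it (limma adjusted p = 0.0113). It was the single member of 25 tested that passed, over all genes and when adjusted over the list alone. The list median was -0.53, at percentile 0.03, with -0.63 in the unirradiated and -0.36 in the irradiated pair. The G2 and mitosis list had a median of -0.28 at percentile 3.01, with -0.34 at percentile 1.84 in the unirradiated and -0.47 at percentile 0.30 in the irradiated pair, and none of its 17 tested members passed over all genes or over the list alone. The ribosomal protein list, with 33 tested members, had a median of 0.01 at percentile 49.65 and no member passed either adjustment. Markers of neurons, muscle, germline, fat body and epidermis had no member that passed over all genes, and germline markers lay at percentile 48.6 in the unirradiated and 1.53 in the irradiated pair. Adjusted over the list alone, the fat body list had Yp2 (2.09 and 1.42) and the epidermis list had Cht2 (2.48 and 0.76).

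The other lists had no member that rose or fell over all genes, except that the DNA repair list and the reference genes each held 1 gene already named, PCNA and Gapdh1. The 4 reference genes had a median of 0.75, the largest of the 27 lists. At percentile 97.17 it lay just inside the middle 95% of random lists. Small heat shock proteins had a median of 0.47 at percentile 93.95, cell death regulators 0.24 at 90.93, growth regulators of the insulin and TOR pathways 0.24 at 86.01, and crystal cell and lamellocyte genes 0.25 at 85.67. In the unirradiated pair alone small heat shock proteins lay at percentile 98.0 and crystal cell and lamellocyte genes at 98.25, and in the irradiated pair at 61.93 and 80.57. Autophagy genes had a median of 0.03, the p53-dependent list one at percentile 51.79, DNA repair 0.04, the JNK pathway -0.11 and other chaperones -0.21. Adjusted over the list alone, Atg2 (3.08 and 0.70) was higher among autophagy genes and the mitochondrial chaperone gene Hsp60A (-0.74 and -1.23) lower among the chaperones. Of the 27 lists, 6 had an ecdysone median outside the middle 95% of random lists, against 1.35 for random draws. Some lists share members and genes of a list may vary together, so 1.35 is no measure of chance here.

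**Figure D1:**
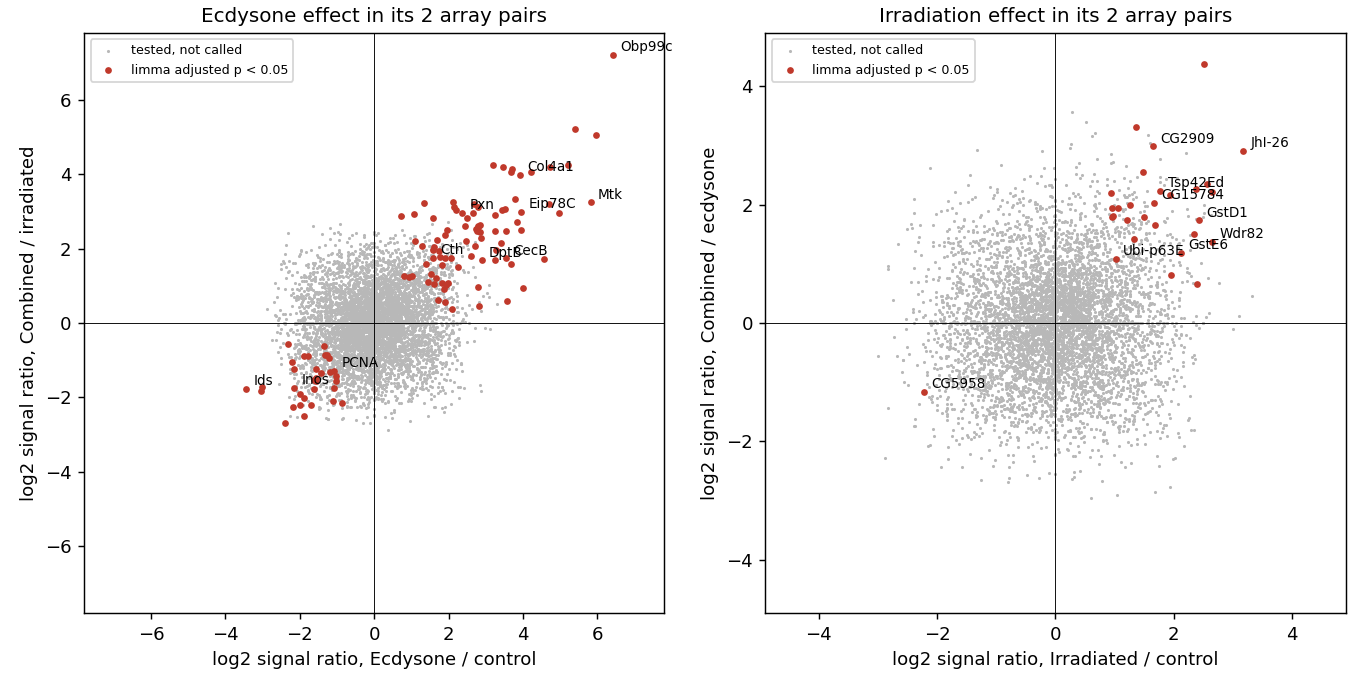
Log2 signal ratios on floored MAS5 signals for the 5981 tested probe sets, with the pair without the other treatment on the horizontal axis and the pair with it on the vertical axis, for ecdysone (left) and irradiation (right). Red points are the 119 ecdysone and 29 irradiation probe sets with a limma adjusted p under 0.05; red points lie mostly in the upper right in both panels, and Obp99c lies at 6.41 and 7.22.

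The limma fit had no replicate cultures to draw on. Its residual is the disagreement of the 2 array pairs of a treatment, so a true interaction counts as noise. The prior weighed far more, with a median of 29.4 degrees of freedom against 1, so the spread mostly followed signal intensity. A small p-value therefore does not show that the 2 pairs agree, and it does not measure the spread between cultures. With 1 variance prior for all signal levels in place of a trend with intensity no probe set passed for ecdysone, with 418 at an unadjusted p under 0.05 against 584 in the fit with the trend. The size rule called 552 probe sets, 315 higher and 237 lower, while the crossed grouping of the same arrays, control and combined against the single treatments, called 302 or 323 depending on how it was paired. Across the 5981 probe sets, which are not independent replicates, the ecdysone differences of the 2 pairs had a Pearson r of 0.20 and a Spearman rho of 0.14.

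Irradiation was followed by fewer calls, 3 of them glutathione S-transferase genes. GstD1, which encodes a glutathione S-transferase, rose from 4856 to 25936 signal units without ecdysone and from 3918 to 13040 with it (limma adjusted p = 1.06e-05). CG15784, an already abundant transcript, rose from 12039 to 38251 and from 7127 to 29169 (limma adjusted p = 5.97e-05). The tetraspanin gene Tsp42Ed rose by 1.77 and by 2.24. JhI-26, known as inducible by juvenile hormone, rose at least 8.23-fold, and Ubi-p63E, a polyubiquitin gene, rose by 1.02 and by 1.08. A probe set shared by Prx6b, CG12896 and Prx6c, genes of the peroxiredoxin family, had the smallest adjusted p of the comparison and was higher by 2.51 and by 4.39, without showing which of them changed.

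Of 5981 probe sets, 29 changed with irradiation, 28 higher and 1 lower. The 1 that fell was CG5958, at -2.22 and -1.17. Others that rose were CG10916 (1.49 and 1.79), CG3609 (1.68 and 1.65), Wdr82 (2.65 and 1.37), CG3397 (1.48 and 2.56), kek1 (1.27 and 1.99), ATPsynF (3.77-fold), RtcB (0.94 and 2.20), puml (1.33 and 1.42) and the thioester protein gene Tep4 (0.97 and 1.80). Of the 12 genes with the largest increases under the size rule 5 passed limma: JhI-26 (3.17 and 2.91), RAF2 (2.57 and 2.35), CG17834 (2.65 and 2.21), CG11710 (1.36 and 3.31) and CG2909 (1.65 and 2.98). The remaining 7 did not pass: bocks (2.21 and 2.88), wash (1.57 and 3.18), CG11825 (1.59 and 3.04), wus (1.77 and 2.77), HBS1 (at least 4.77-fold), Tsp26A (2.06 and 2.45) and CG9444 (2.63 and 1.83). The other probe set of CG17834 had a mean difference of 0.06 and that of RAF2 one of -0.25, both too weak for the test.

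None of the 12 genes with the largest decreases under the size rule passed limma, and 11 of them had a signal at the floor. Their smallest adjusted p was 0.0934, for eIF5B at -2.89 and -2.28. The 3 probe sets of eIF5B disagreed, with mean differences from -2.59 to 0.29, and the brightest was at 0.08 and 0.50. The others were Lsp2 (-1.94 and -2.44), Spn42Dc (-2.84 and -1.43), Atxn7 (-2.16 and -2.08), Gr8a (-2.11 and -2.06), CG44085 (-2.40 and -1.74), comm3 (-1.82 and -2.29), Or22c (-1.58 and -2.43), PolA1 (-2.38 and -1.63), HP4 (-2.06 and -1.91), CG14210 (-1.82 and -2.10) and Gfrl (-2.37 and -1.75). For Gfrl 6 probe sets ranged from -2.06 to 1.43.

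Of 18 tested members of the oxidative stress and detoxification list GstD1, GstE6 (2.12 and 1.18) and GstE1 (1.94 and 0.81) rose, and 9 were higher when adjusted over the list alone. The added ones were GstD3, GstE3, the thioredoxin gene Trx2 (2.09 and 1.03), Trxr1, Gclc and Gtpx. The list median of 0.41 lay at percentile 99.23, with 0.64 in the pair without and 0.62 in the pair with ecdysone.

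The p53-dependent radiation response list had the highest median for irradiation, 1.02 at percentile 100. None of its 9 tested members passed over all genes, while 5 were higher when adjusted over the list alone. These were p53 itself (1.76 and 1.07), the double-strand break repair genes rad50 (1.38 and 2.47) and mre11 (0.70 and 1.33), the ribonucleotide reductase gene RnrL (0.71 and 2.40) and Gadd45 (0.25 and 3.03). The list median was 0.48 in the pair without ecdysone, at percentile 95.93, and 1.34 in the pair with it. The wider list of DNA damage signalling and repair had a median of 0.24 at percentile 95.96, with no member of 17 passing either adjustment. The cell death list lay at -0.42, percentile 2.44, with percentiles of 6.12 and 31.11 in the single pairs. Its 8 tested members included none that passed over all genes or over the list alone. In this list rpr, hid, Drice, Diap1 and Decay had no probe set of their own and were left out. The p53 list lacked rpr, hid and Xrp1 for the same reason.

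DNA replication genes had a median of -0.29 at percentile 0.815 for irradiation from the mean of both pairs, while the median was 0.00 in each single pair, and none passed over all genes. Adjusted over the list alone, PolA1 (-2.38 and -1.63) was lower and RfC4 (0.43 and 1.86) higher. Ribosomal protein genes had a median of 0.34 at percentile 98.37, and percentiles of 74.44 without and 97.86 with ecdysone, with no member past either adjustment. The G2 and mitosis list had a median of -0.17 at percentile 9.9, with -0.42 at percentile 0.45 in the pair without ecdysone and 0.00 at 51.09 in the pair with it. In this list the tribbles gene trbl (1.08 and 1.53) was higher when adjusted over the list alone. The immune list had a median of 0.38 at percentile 98.9, with 0.52 in the pair without and -0.11 in the pair with ecdysone. In it PGRP-LE, a peptidoglycan recognition protein gene (1.67 and 1.52), was higher when adjusted over the list alone and no member passed over all genes. Of the hemocyte list Tep4 rose among 15 tested, and adjusted over the list alone it was the single higher member, with the laminin gene LanA (-0.79 and -2.62) lower.

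Germline markers had a median of 0.43 at percentile 98.98 over 10 members above the floor, with 0.56 in the pair without and 0.00 in the pair with ecdysone. Of their 4 tested members none passed either adjustment. Crystal cell and lamellocyte genes had a median of -0.45 at percentile 3.79, with 49.46 in the pair without and 1.35 in the pair with ecdysone, small heat shock proteins -0.31 and other chaperones 0.08. Glycolysis had a median of -0.14, the insulin and TOR list -0.16, the lysosome 0.12, autophagy -0.04, the ecdysone response -0.03 and the JNK pathway 0.03. The P450 list had 0.10, the cytoskeleton 0.09, adhesion and matrix 0.01 and the reference genes 0.14, and in these lists no member passed over all genes. Muscle markers had -0.22, epidermis markers -0.10, fat body markers -0.01 and neuron markers lay at percentile 56.41, again with none past the threshold over all genes. Adjusted over the list alone, ImpL2 (1.43 and 0.98), which encodes an insulin-binding protein, was higher in 2 of these lists, Gadd45 in the JNK list and Cyp4e2 (0.98 and 1.73) in the P450 list, while Lsp2 and LanA were lower. Of the 27 lists, 7 lay outside the middle 95% for irradiation.

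**Figure D2:**
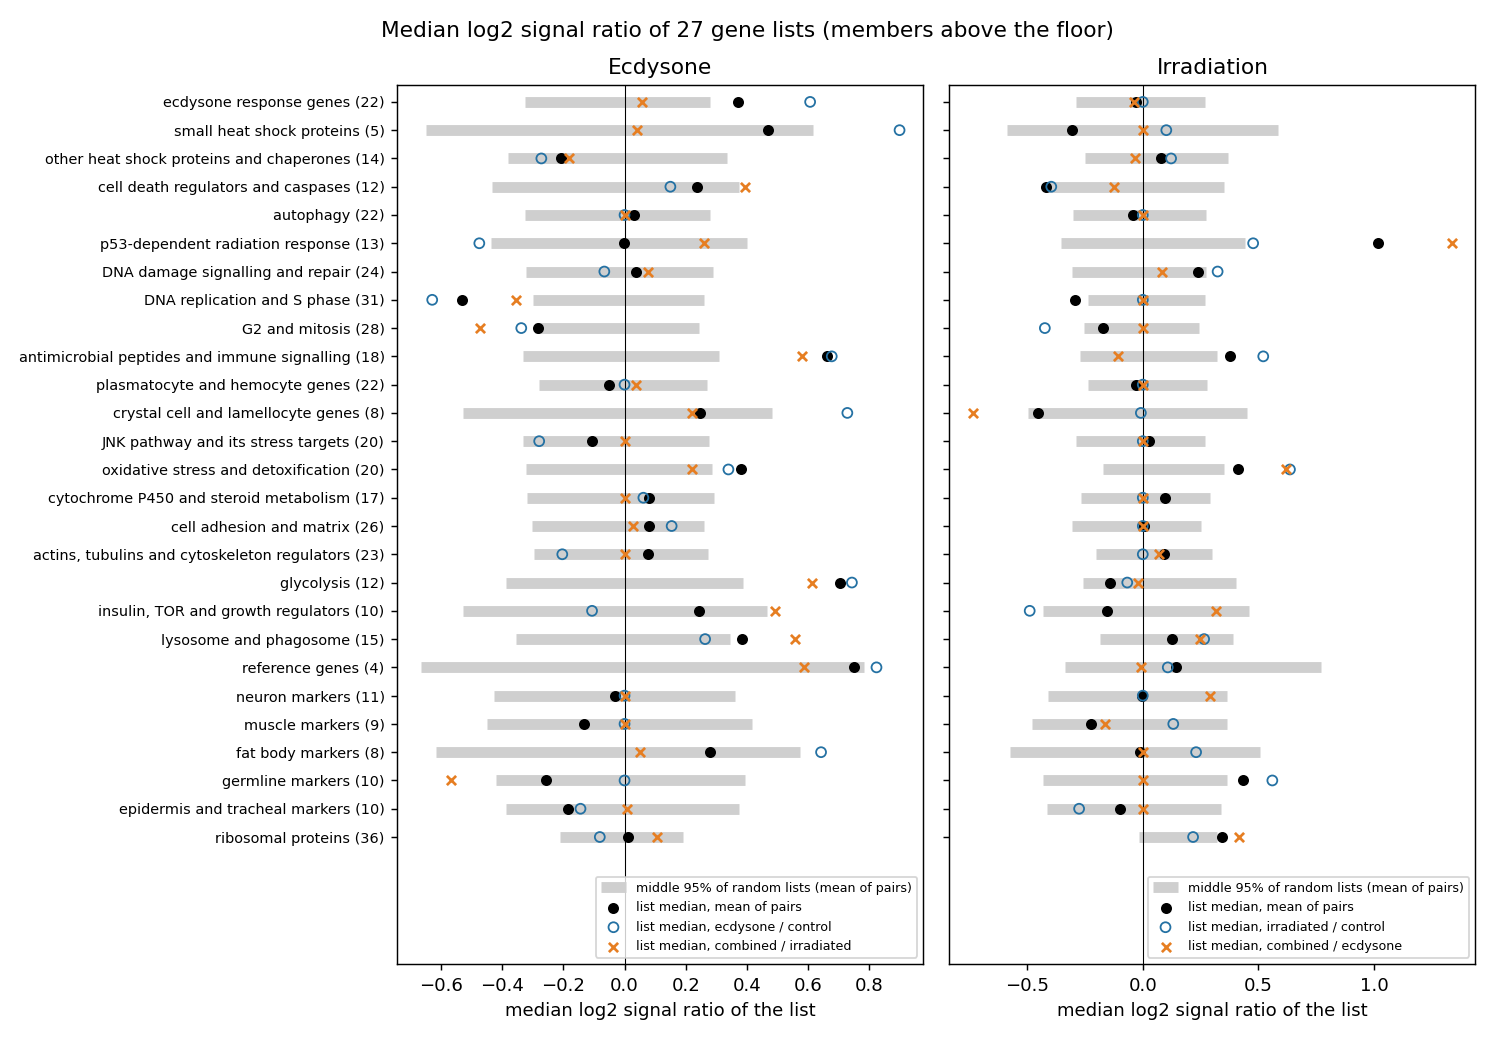
Median log2 signal ratio of each of the 27 gene lists, with the number of members above the floor in parentheses, for ecdysone (left) and irradiation (right). Black points are the mean of both pairs, open circles and crosses the single pairs, and grey bars the middle 95% of random lists matched on signal; the immune list lies at 0.66 for ecdysone and the p53 list at 1.02 for irradiation.

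Both irradiated arrays were run on fluidics modules 1 and 2 and scanned before the others, so run order and irradiation cannot be told apart for single probe sets. The 9 hybridization spike-ins had mean irradiation differences from -0.63 to 0.092, on signals that already shared a trimmed mean over the arrays. No probe set passed without the intensity trend, with 303 at an unadjusted p under 0.05 against 411 with it, and 6 passed after quantile normalization. The 3′ against 5′ log2 difference of the actin control transcript was 1.22 above control in the irradiated array and -0.18 from it in the combined array, and that of the eIF-4a transcript was 0.57 above and -0.35 from it. That of the GAPDH transcript was higher with irradiation in both pairs, by 0.97 without and 0.99 with ecdysone. Of the 397 probe sets called by the size rule, 215 were higher and 182 lower. With a floor of 500 signal units, chosen after seeing the data, the size rule called 25 higher and none lower, while the crossed grouping gave 0 calls. Limma, with unfloored signals of the 1164 probe sets whose mean exceeded 500, called 32 higher and 2 lower, or 8 higher and 0 lower without the trend. By the size rule the same floor left 62 higher and 24 lower for ecdysone. Irradiation differences of the 2 pairs correlated across the 5981 probe sets with a Pearson r of 0.064 and a Spearman rho of 0.058.

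Tsp42Ed, CG5958 and CG13051 passed for both treatments, as did 2 probe sets without a single gene name. Tsp42Ed rose stepwise from 997.7 in control to 1730 with ecdysone, 3410 after irradiation and 8161 with both. CG5958 rose with ecdysone (3.20 and 4.25) and fell with irradiation. CG13051 rose with ecdysone (2.10 and 0.38) and with irradiation (2.39 and 0.67), while its other probe set did not pass and was at 0.12 and 0.14 for ecdysone and at 0.18 and 0.20 for irradiation. Independent lists would share 0.577 probe sets, but both tests of a probe set use the same estimate of spread, so the 5 are not evidence of a link between the treatments. Of the 5, 3 moved in the same direction.

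**Figure D3:**
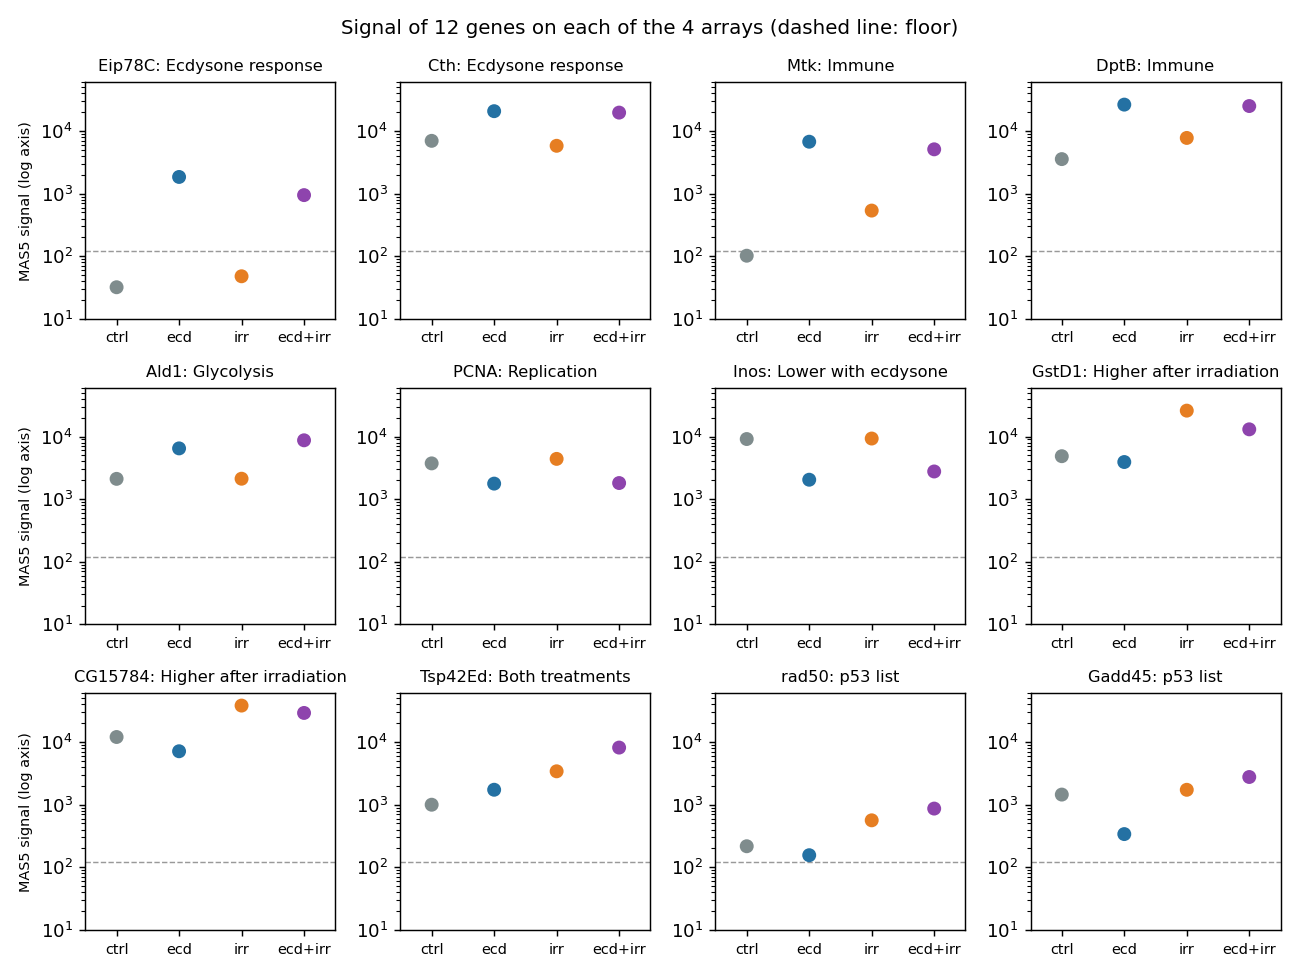
MAS5 signal (log axis) of 12 genes on the 4 arrays, control, ecdysone, irradiated and combined; each point is 1 array and the dashed line is the floor of 119.4. Mtk goes from 102 in control to 6755 with ecdysone, and GstD1 from 4856 to 25936 after irradiation.

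The combined treatment allowed the ecdysone effect to be compared between irradiated and unirradiated cells, without a test, because 4 arrays leave no spread for the interaction. All 4 antimicrobial peptide genes that rose with ecdysone had a smaller difference in irradiated cells, for example 3.25 against 5.82 for Mtk and 1.75 against 3.54 for CecB. DptB ended at nearly the same signal with ecdysone, 26438 without and 25092 with irradiation, and started from 3563 and 7763. Over the immune list, 12 of 18 members had a smaller ecdysone difference in irradiated cells and the median change was -0.83, at percentile 0.12. For the p53 list the irradiation difference was larger with ecdysone in 9 of 13 members, with a median change of 0.83 at percentile 98.97. Gadd45, a growth arrest and DNA damage gene, had 1449 signal units in control, 339 with ecdysone, 1727 after irradiation and 2766 with both. Among all probe sets 3987, or 28.55%, differed at least 2-fold between the ecdysone effects, 1940 higher and 2047 lower in irradiated cells. At a floor of 500 signal units these were 90 and 78.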

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

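All tests in this part were chosen after the results were seen. The 10 genes with the largest difference between the ecdysone effects in irradiated and unirradiated cells moved in opposite directions in the 2 pairs, and these differences were not tested. The log2 difference was 4.74 for CG17666, 4.47 for l(1)G0469, 4.25 for CG34324, 4.25 for CG13046 and 4.13 for Tim17b2. It was -4.71 for Tsp42Ef, -4.29 for rdgA, -4.28 for Ars2, -4.25 for Cda4 and -4.16 for beat-IIb. All of these genes but Tsp42Ef had signals at the floor, so their differences depend on it. Further probe sets exist for l(1)G0469, rdgA, Ars2, Cda4 and beat-IIb, and their interaction was not compared.

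Irradiation calls were mostly increases among bright probe sets, 25 higher and none lower by the size rule at a floor of 500 units. Limma over the 1164 probe sets with a mean above 500 gave 32 higher and 2 lower, or 8 higher and 0 lower without the intensity trend. At the median floor, the calls were 1.23 times those of the crossed grouping, so noise of weak signals could account for most of them. A floor of 500 largely removes noise of weak signals by construction, so the calls there cannot weigh it. The crossed grouping gave 0 calls at that floor against 25 for irradiation, so the bright calls exceeded this gauge of noise. The mean 3′ shift of 3 control transcripts was -0.091 in the pair with ecdysone, over actin at -0.73, eIF-4a at -0.53 and GAPDH at 0.99, so a shift towards the 3′ end of transcripts stays open. The order of fluidics modules and scans stays open as well for single probe sets, because it follows irradiation on every array. The 9 hybridization spike-ins had a median difference of -0.19 and lay from -0.63 to 0.092. The bright calls of the size rule had mean differences from 1.05 to 3.45. Signals already had a shared trimmed mean on all arrays, which removes a general rise from washing and scanning, so the spike-ins cannot weigh one.

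The immune list had a smaller ecdysone effect in irradiated cells, with a median change at percentile 0.12, and noise between single arrays is not excluded by it. The list median of irradiated against control lay at percentile 99.39, and that of combined against ecdysone was -0.105. Both values are parts of the change itself, so a higher starting level in irradiated cells cannot be told apart from low values of these genes in the single control array.

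The p53 list had a larger irradiation effect with ecdysone, at percentile 98.97. Noise between single arrays may still account for it, since this list was picked from 27, of which 5 lay outside the middle 95% for this difference. Random draws would give 1.35, but genes of a list may vary together, so that excess decides nothing. Low values of these genes in the single ecdysone array could also give the larger effect, since the list median of ecdysone against control was -0.47. Neither can be told apart from an interaction of the treatments, which was not tested.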

How the results depend on the processing

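No paired analysis was possible because each condition had 1 array and the labels pair no samples. The alternatives run for single genes were the 3 scalings, the lower and higher floors and no floor. All 24 genes named for ecdysone and the 10 named for the interaction kept their direction, as did those named for irradiation. Of the latter, Spn42Dc at the higher floor (-1.60) lost its call. A floor cannot reverse a difference, and these genes were picked for large ones, so their direction was largely fixed in advance. Of the list medians 278 stayed within their spread and 100 moved, and none reversed among those outside the random range. Floors change the counts by construction, since a lower floor lets weaker signals pass the size rule. Size rule calls for ecdysone were 1517 at the lower floor, 295 at the higher floor, 2100 with no floor, 86 at a floor of 500, 1384 at 1.5-fold, 132 at 3-fold, 2937 in the unirradiated pair only and 2602 in the irradiated pair only. For irradiation they were 1268, 162, 1904, 25, 1160, 50, 2660 without ecdysone and 2521 with it. Probe sets called by limma for ecdysone were 0 without the intensity trend, 79 after quantile normalization, 75 at the higher floor, 56 with no floor and 68 at a floor of 500 without the trend. For irradiation they were 0, 6, 6, 4 and 8, and the cause was not tested. With the trend, limma called 123 probe sets for ecdysone and 39 for irradiation of 11663 tested at the lower floor. Of 1164 tested at a floor of 500 it called 98 and 34. Interaction counts were 7458 at the lower floor, 2256 at the higher, 8548 with none and 168 at 500. Each floor also set which probe sets entered the correlation of the pairs, those with a mean above it. For ecdysone the correlation was 0.0966 over 11663 probe sets at the lower floor, 0.0656 over 13966 with none and 0.636 over 1164 at 500. For irradiation it was 0.0242 at the lower floor, 0.117 over 4245 probe sets at the higher, 0.0227 with none and 0.324 at 500. The floor of 500 was chosen after seeing the data. Floored differences spread more among weak probe sets: those between irradiated and control had an SD of 0.653 above 500 units and 0.992 between the floor and 500. These SDs also hold treatment effects, so they do not measure noise alone, and the cause was not tested. For combined against ecdysone the SDs were 0.709 and 0.979. The contrast was smaller for ecdysone against control, at 0.966 and 1.07, and for combined against irradiated, at 0.887 and 1.00.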

Other observations

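All tests in this part were chosen after the results were seen, and the genes were chosen after their values were seen. The iron storage genes Fer1HCH (1.77 and 1.77) and Fer2LCH (1.40 and 1.60), which encode both ferritin chains, rose with ecdysone. NimC3, a phagocytosis receptor gene of the Nimrod family (2.65 and 2.97), rose as well, as did amd (4.57 and 1.72). Prosbeta4, a proteasome subunit gene, fell by 1.57 and by 1.24.

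Genes of the mitochondrial ribosome lay low with ecdysone: the median of 62 members was -0.41, and it stayed negative under each scaling. No member passed limma over all genes, and 4 were lower by the size rule.

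Proteasome genes as a family also lay low with ecdysone. The median of 26 members was -0.40, at percentile 0.31 of random lists, and it was negative under each scaling. Prosbeta4 was the single member that passed limma and the single one lower by the size rule. The family was chosen after the values were seen and includes Prosbeta4, so its median does not explain the fall of that gene. For irradiation the proteasome median lay at percentile 28.28, and its value of 0.07 turned to -0.09 after quantile normalization. For mitochondrial ribosomal proteins the irradiation percentile was 40.39. The 30 glutathione S-transferases lay at percentile 93.84 for irradiation, with a median of 0.21, so the 3 members that rose were not part of a shift of the whole family beyond random lists. The 8 NPC2 genes lay at percentile 33.79 for ecdysone, although Npc2a and Npc2g rose.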
